A study of Mus musculus with 38 samples.

How the data were processed

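RNA of 4 sorted populations of mouse lung tumours (BM-TAM, T-AM, CD4 T cells and total viable cells) was sequenced in 38 libraries from 3 treatments. BM-TAM and T-AM were both sorted as CD45-positive, Ly6G-negative, Ly6C-negative and F4/80-positive cells. BM-TAM were CD11b-positive with CD11c and CD206 low to positive, and T-AM CD11b-negative, CD11c-positive and CD206-positive. CD4 T cells were CD45-positive, Ly6G-negative, Ly6C-negative, F4/80-negative, CD3-positive and CD4-positive, and total cells as single cells that exclude the dye DAPI. Libraries were made with a stranded total RNA kit for small input and sequenced in pairs. The submitters' processing notes name bcl2fastq 2.17, HISAT2 2.1.0, HTSeq 0.9.1, featureCounts 1.4.4, edgeR 3.28.1, limma 3.42.2 and the mouse build mm10, without saying which counter made which file. Per the deposited files, the authors gave raw whole-number read counts per gene, in a file per library and in a table of the series, and the 2 hold the same values. The authors also deposited a table of log2 CPM for 11500 genes, scaled by TMM factors, which was used only to check the match of columns to samples. Gene positions and types came from GENCODE release M21.

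All results were computed from the deposited counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15) on the groups of each fit and scaled by TMM factors. The tests were two-sided edgeR quasi-likelihood tests (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no minimum fold change. The treatments were compared within each population from 1 fit of its 3 arms. BM-TAM and T-AM were compared in the IgG arm, and the difference between their treatment responses from 1 fit of all 20 macrophage libraries. No covariate was used. Whether replicate numbers pair the libraries was judged by the correlation of their deviations from the group means, with a correlation over 0.1 in every one of at least 3 pairs as the rule. Between populations of a treatment 41 of 54 pairs with the same number passed 0.1 (median 0.20, against -0.08 for unlike numbers). BM-TAM and T-AM with the same number were at 0.18 to 0.42 in the IgG arm (3 of 3 pairs over 0.1), at 0.28 to 0.44 in the combination arm (4 of 4) and at 0.06 to 0.13 in the A2V arm (1 of 3). The pairing so comes from the data and holds for BM-TAM against T-AM in the IgG arm and for the difference between their responses to the combination, not to A2V. Across treatments of a population 5 of 32 pairs passed 0.1 (median -0.02). No set met the rule (total cells, IgG and A2V: 2 of 3, median 0.39).

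Written down before the data were examined were the comparisons, 34 gene lists, the alternatives and the rule for naming genes. Which of the lists are described under each comparison was chosen after their values were seen. The lists cover interferon responses (type I, gamma), MHC class I and II, inflammatory cytokines, macrophage states (alveolar, monocyte and interstitial, lipid-associated, alternative activation), T cell states (Th1, Th2 and Th17, regulatory, follicular helper, naive, checkpoints), other cell types (T, CD8 T and NK, B, plasma, neutrophil, mast cell, dendritic, platelet, erythroid, endothelial, tip cell, pericyte, fibroblast, lung epithelial), VEGF and angiopoietin ligands and receptors, hypoxia, cell cycle, cholesterol biosynthesis and dissociation. The genes named are the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and non-overlapping groups, without predicted genes, antigen receptor segments, Y genes and Xist. Added to these are up to 4 list members per list past the threshold, for lists that fit the population the 2 to 4 members with the smallest p, and Msh2, Kras, Trp53, Xist, Ptprc, Pdcd1, Cd274, Vegfa, Angpt2, Kdr and Tek. Some of these genes were left out of the text for length, after their values were seen.

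Lists with at least 5 tested members were tested by limma camera on voom log2 values with a preset correlation of 0.01, by camera with an estimated correlation and by fry, and their medians are medians of the log2 fold changes of that fit. Fry's first test asks whether the genes of a list move on balance in 1 direction and its mixed test whether they change in either, and neither compares the list with other genes or lists. Adjusted p of lists are over the lists of a comparison. Counts adjusted over the list alone use the edgeR p of its members. Levels are CPM with TMM scaling over the libraries of each fit, so that a gene's level in 1 group can differ slightly between fits. Genes of the sort gates (Itgam, Itgax, Mrc1, Cd4) are given as checks only.

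The precision is limited by 2 to 4 mice per group and by depth. 3 libraries, BM-TAM IgG replicate 2, BM-TAM A2V replicate 3 and CD4 T cell A2V replicate 3, are under 5 M counts. For genes with few reads in a group only levels are given. The tests were tried on simulated counts with known changes. The alternatives tried were RLE size factors in edgeR, DESeq2 1.42.0 and limma voom as tests, no filter on low counts, a replicate block, sex as a covariate, only the 2 arms compared, male or female mice alone, each library left out in turn, all 20 macrophage libraries for the cell type comparison, and the estimated correlation. Added after the data were seen were protein-coding nuclear genes alone, a filter at a mean of 5 CPM, robust moderation, leaving out libraries under 5 M counts, and sex as a covariate for the cell type comparison and the response differences. Correlations of list scores across mice used 100000 permutations . No library was left out of the main tests.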

Results

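RNA was sequenced from 38 libraries of lung tumours of mice whose tumours carry an activated Kras allele and lack p53 and the mismatch repair gene Msh2. From week 15 after tumour induction the mice received weekly intraperitoneal injections for 4 weeks. The 3 arms were isotype antibodies (IgG, 10 and 20 mg/kg), A2V (20 mg/kg), a bispecific antibody against the angiogenic factors VEGFA and ANGPT2, and A2V plus an antibody against the checkpoint receptor PD1 (10 mg/kg), called the combination here. From the tumours, 4 populations were sorted: bone-marrow-derived tumour-associated macrophages (BM-TAM), tumour alveolar macrophages (T-AM), CD4 T cells and total viable cells. BM-TAM and T-AM came from 3 IgG, 3 A2V and 4 combination mice each, CD4 T cells from 3, 2 and 4, and total cells from 3, 3 and 3. The labels number the replicates and give their sex (IgG 1 male and 2 females, A2V 3 males, the combination 1 male and 3 females) but do not say that each is a separate mouse. Replicates are called mice here, and the p-values measure the spread between these samples, which may be technical if mice were shared. Counts assigned to genes, in units of 1e6 (M), ranged over 2.50 to 14.3 M per library in BM-TAM, 7.85 to 21.5 M in T-AM, 4.49 to 16.5 M in CD4 T cells and 11.1 to 19.2 M in total cells. Levels are CPM (counts per M counts, mean ± SD over mice), first-named group first, n as in these groups. Log2 fold changes have their standard error (SE) from the fitted model.

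The marker genes of the sorted populations followed the gates. In IgG mice, Itgam, which encodes CD11b of the BM-TAM gate, was at 82.2 ± 27.0 CPM in BM-TAM and 4.63 ± 3.31 CPM in T-AM. Itgax (CD11c) was at 986 ± 143 and 1081 ± 111 CPM, and Mrc1 (CD206) at 1469 ± 258 and 1934 ± 93.7 CPM. Cd4 was at 588 ± 40.4 CPM in CD4 T cells and 1.43 ± 1.09 CPM in T-AM. In total cells the pan-leukocyte gene Ptprc was at 1073 ± 279 CPM, the endothelial gene Pecam1 at 150.1 ± 47.7 CPM and the epithelial gene Epcam at 112 ± 26.0 CPM. The targets of A2V and their receptors were measured there too: Vegfa at 193 ± 159.8 CPM, Angpt2 at 3.37 ± 4.69 CPM, the VEGF receptor gene Kdr at 66.0 ± 35.0 CPM and the angiopoietin receptor gene Tek at 44.1 ± 17.2 CPM. Pdcd1, which encodes PD1, was at 77.7 ± 23.5 CPM in CD4 T cells of IgG mice, and Cd274, which encodes its ligand, at 121 ± 56.2 CPM in BM-TAM and 173 ± 17.5 CPM in T-AM. Xist was at most 0.991 CPM in the 19 libraries labelled male and at least 708 CPM in the 19 labelled female. Msh2 was at 7.59 CPM or more in every library, Kras at 19.6 to 78.7 CPM and Trp53 at 4.73 to 82.7 CPM, and gene-level counts cannot show a deleted part of a gene.

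The first comparison asked how BM-TAM and T-AM of IgG-treated tumours differ (3 libraries each). Genes of monocytes and interstitial macrophages rose in BM-TAM: 17 of 19 members passed the test (median 3.87, adjusted p = 1.53e-16, adjusted p = 0.200 with an estimated correlation). Among them were the transcription factor genes Mafb (392 ± 231 against 33.8 ± 19.2 CPM, log2 difference 3.55, SE 0.54, adjusted p = 0.0101) and Maf (84.5 ± 66.8 against 2.87 ± 1.06 CPM, log2 difference 4.91, SE 0.68, adjusted p = 0.00790). F13a1, the coagulation factor subunit of monocytes and macrophages, was at 139 ± 105 against 0.0947 ± 0.164 CPM, the scavenger receptor gene Cd163 at 36.3 ± 19.9 against 0.0473 ± 0.0820 CPM and the folate receptor gene Folr2 at 17.0 ± 11.9 against 0.0624 ± 0.108 CPM. The chemokine genes Ccl8 and Cxcl13 were at 45.3 ± 9.00 against 0.125 ± 0.216 CPM and 57.0 ± 11.6 against 0.200 ± 0.189 CPM. These 5 genes held 2 to 7 counts over the 3 T-AM libraries, so no fold is given. The ferroxidase gene Cp was higher by 6.75 (SE 0.47) on the log2 scale.

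Inflammatory cytokine genes rose in BM-TAM as well, 13 of 18 over all genes tested and 17 adjusted over the list alone (median 1.51, adjusted p = 1.02e-14, adjusted p = 0.200 with an estimated correlation). Il1b was at 1190.4 ± 345 against 319.7 ± 52.5 CPM (log2 difference 1.90, SE 0.23, adjusted p = 0.00527), and the monocyte chemokine gene Ccl2 differed by 4.34 (SE 0.54). In the alternative activation list 9 of 16 genes rose (median 2.59, adjusted p = 2.20e-05, adjusted p = 0.167 with an estimated correlation), among them arginase Arg1 (96.8 ± 47.6 against 3.80 ± 2.50 CPM, log2 difference 4.63, SE 0.57) and the scavenger receptor gene Msr1 (1.05, SE 0.15). In the MHC class II list 5 of 15 rose (median 0.80, adjusted p = 6.68e-05, adjusted p = 0.369 with an estimated correlation): H2-Eb1 by 1.27 (SE 0.21) and H2-Aa by 0.88 (SE 0.21). Of the lipid-handling genes, Apoe rose (10291 ± 7041 against 496 ± 507 CPM, log2 difference 4.38, SE 0.89), while the lipid droplet gene Plin2 was at 537 ± 100.2 against 832 ± 52.5 CPM (adjusted p = 0.0524). That list was not called (adjusted p = 0.845): its median was -0.40 and its mean 0.16. Vegfa rose by 2.35 (SE 0.52) (121 ± 60.7 against 24.0 ± 12.5 CPM, adjusted p = 0.0337).

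Alveolar macrophage genes fell in BM-TAM (median -1.52, 18 of 19 lower, adjusted p = 8.07e-08, adjusted p = 0.369 with an estimated correlation). 2 passed lower over all genes tested and 12 adjusted over the list alone. The scavenger receptor gene Marco fell by 2.21 on the log2 scale (SE 0.42, adjusted p = 0.0197). The fatty acid binding protein gene Fabp1 (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023 on mm10) was at 6.46 ± 1.85 against 46.3 ± 3.77 CPM (log2 difference -2.85, SE 0.25, adjusted p = 0.00296). Siglecf, a marker of alveolar macrophages, was at 53.6 ± 41.1 against 205 ± 37.4 CPM (adjusted p = 0.0715), and the lipid regulator gene Pparg at 61.6 ± 26.9 against 134 ± 3.25 CPM (adjusted p = 0.0686). Others that fell were the peroxisomal thiolase gene Acaa1b (-3.05, SE 0.41) and the potassium channel gene Kcnk5 (-2.57, SE 0.62). Cell cycle genes fell too (median -0.93, 20 of 20 lower, adjusted p = 3.64e-06, adjusted p = 0.264 with an estimated correlation), with Mki67 at 163 ± 9.69 against 272 ± 35.8 CPM (log2 difference -0.74, SE 0.14, adjusted p = 0.0186).

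Markers of other cells also differed between the sorted fractions. B cell genes rose in BM-TAM, 5 of 9 (median 3.59, adjusted p = 7.76e-05, adjusted p = 0.167 with an estimated correlation), with Ighm at 61.9 ± 13.9 against 5.88 ± 5.13 CPM, and the platelet gene Pf4, which macrophages also express, was at 28.8 ± 22.1 against 2.08 ± 0.641 CPM. In the naive T cell list 6 of 12 genes rose (median 2.31, adjusted p = 2.83e-04, adjusted p = 0.238 with an estimated correlation). Immediate early and heat shock genes, which cell dissociation induces, rose too, 8 of 18 (median 0.79, adjusted p = 8.76e-09, adjusted p = 0.264 with an estimated correlation). Of 14 checkpoint genes 4 rose, Lgals9 (1.13, SE 0.14), Vsir (1.05, SE 0.21) and Cd276 (1.50, SE 0.33) with the smallest p. The checkpoint, type I interferon, interferon gamma, Th1 and hypoxia lists lay higher (medians 0.83, 1.01, 0.54, 1.31 and 0.25) and cholesterol biosynthesis lower (median -0.37). Their adjusted p were 0.00801, 0.00146, 0.0392, 0.0294, 0.0263 and 0.0244, and adjusted p = 0.200 to 0.737 with an estimated correlation.

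Between BM-TAM and T-AM, edgeR called 930 of 13218 genes, 679 higher and 251 lower in BM-TAM, DESeq2 1765 and limma voom 1245. The replicate numbers pair these samples, and with the replicate as a block 1629 genes were called, 905 of them shared with the unblocked test. Camera called 15 of 29 lists, and 0 with an estimated correlation. The fry test of movement in 1 direction called 11 and its mixed test of change in either direction 20. The gene count was 179 without T-AM IgG replicate 2, 297 without T-AM IgG replicate 3 and 566 without T-AM IgG replicate 1. It was 244 without BM-TAM IgG replicate 2, the library under 5 M counts, and 1782 without BM-TAM IgG replicate 3. The MHC class II, alternative activation, alveolar, monocyte, cytokine, naive T cell, B cell, cell cycle and immediate early calls held with any 1 library left out. Lost were the interferon gamma, type I interferon and checkpoint calls without BM-TAM IgG replicate 3 (medians 0.14, 0.62 and 0.78); the interferon gamma and Th1 calls without BM-TAM IgG replicate 2 (medians 0.40 and 1.26). Without T-AM IgG replicate 1 the interferon gamma call was lost too (median -0.14), and without T-AM IgG replicate 3 the hypoxia call (median 0.27). Without BM-TAM IgG replicate 1 the cholesterol call was lost too (median -0.01), and without T-AM IgG replicate 2 the cholesterol call (median -0.33). All 15 held with sex as a covariate.

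**Figure D1:**
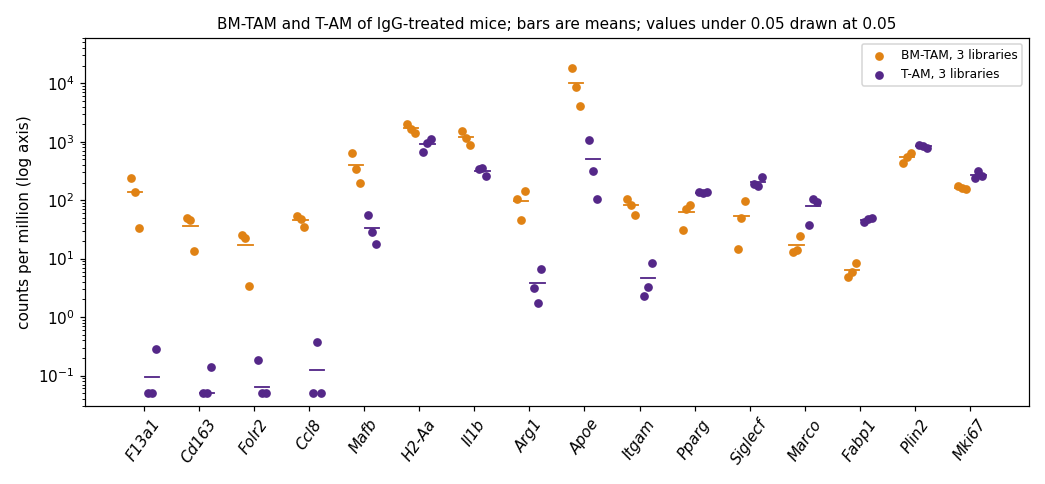
CPM (log axis) of 16 genes in the 3 BM-TAM and 3 T-AM libraries of IgG mice, a point per library and a bar at each mean, with values under 0.05 drawn at 0.05.

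The treatment comparisons set A2V against IgG, the combination against IgG and the combination against A2V within each population. Over the 12 of them edgeR called 1 gene, Sftpc. In simulated data of the same sizes the test of A2V against IgG recovered 55.2% of 4-fold changes in BM-TAM, 70.1% in T-AM, 53.7% in CD4 T cells and 46.3% in total cells. Below, rose or fell means that a list passed camera's test with a preset correlation. It called 11, 16 and 14 lists in the 3 comparisons of BM-TAM, 9, 7 and 13 in T-AM, 18, 15 and 15 in CD4 T cells and 18, 12 and 13 in total cells. With an estimated correlation no list passed in any of the 12, and fry's test of 1 direction called none (its mixed test called 1, lung epithelial genes in BM-TAM). In each of the 10 comparisons with 3 or more mice per arm, some other grouping of the same mice gave at least as many lists. The lists describe these mice and are not shown to differ by treatment. No A2V mouse was female.

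In BM-TAM, type I interferon response genes fell with A2V against IgG (median -0.84, 20 of 20 lower, adjusted p = 4.63e-06, adjusted p = 0.790 with an estimated correlation). The transcription factor gene Irf7 was at 15.6 ± 2.91 against 43.7 ± 24.7 CPM and the antiviral genes Mx1 and Ifit3 at 8.21 ± 4.00 against 19.0 ± 3.56 CPM and 3.89 ± 3.47 against 17.9 ± 8.92 CPM. No member passed singly (smallest adjusted p over the list alone 0.0887). Interferon gamma genes (median -0.55, adjusted p = 0.00763) and MHC class I genes (median -0.39, 15 of 15 lower, adjusted p = 0.00143) fell as well, and adjusted p = 0.790 with an estimated correlation. The chemokine gene Cxcl10 was at 19.3 ± 1.66 against 37.1 ± 7.03 CPM. Hypoxia genes rose (median 0.24, 16 of 20 higher, adjusted p = 0.00482, adjusted p = 0.726 with an estimated correlation), led by the glycolysis switch gene Pdk1 at 38.2 ± 12.8 against 13.6 ± 7.55 CPM (log2 fold change 1.47, SE 0.41). Inflammatory cytokine genes fell (median -0.25, adjusted p = 0.00743) and alveolar macrophage genes rose (median 0.42, adjusted p = 0.00143), and adjusted p = 0.790 with an estimated correlation. The matrix gene Spp1 was at 783 ± 118 against 2064 ± 2254 CPM, and its log2 fold change turned to 0.04 without IgG replicate 3. T cell (median 1.23, adjusted p = 0.00143) and B cell markers (median 0.91, adjusted p = 0.0240) rose beside these lists, and adjusted p = 0.790 with an estimated correlation. Of 14545 genes tested, edgeR called 0 (460 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0. The gene of DESeq2 was Cd93; genes behind counts of 5 or fewer are named here and below after their values were seen. With any 1 library left out the type I interferon call held. Lost were the cytokine, alveolar, T cell and B cell calls without IgG replicate 1 (medians 0.06, -0.13, 0.29 and 0.19); the interferon gamma, MHC class I and hypoxia calls without IgG replicate 3 (medians -0.28, -0.10 and 0.27). Without A2V replicate 1 the cytokine, alveolar and hypoxia calls were lost too (medians -0.13, 0.11 and 0.11), and without IgG replicate 2 the interferon gamma call (median -0.47). Without A2V replicate 2 the B cell call was lost too (median 0.34), and without A2V replicate 3 the B cell call (median 0.76). The interferon gamma, MHC class I and hypoxia calls were lost with sex as a covariate (medians -0.16, 0.06 and 0.22).

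With the combination against IgG, Sftpc fell in BM-TAM. This surfactant protein gene of alveolar type 2 epithelium (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081 on mm10) was at 12.5 ± 5.45 against 68.7 ± 11.3 CPM, with a log2 fold change of -2.45 (SE 0.30) and an adjusted p of 0.0146 in edgeR. The lung epithelial list fell with it (median -1.47, 13 of 17 lower, adjusted p = 9.12e-06, adjusted p = 0.208 with an estimated correlation). The Sftpc call was lost without IgG replicate 2, without combination replicate 2, without libraries under 5 M counts, with only the 2 arms compared and in female mice alone (0 genes each), at log2 fold changes of -2.75 to -2.32 and, with fewer libraries, an SE of 0.33 to 0.37, and a further gene was called without IgG replicate 3 (2 genes). Inflammatory cytokine genes fell (median -0.56, 17 of 18 lower, adjusted p = 1.73e-12, adjusted p = 0.211 with an estimated correlation). None passed over all genes and 7 passed adjusted over the list alone, among them Il1b (677 ± 152 against 1161 ± 336 CPM, log2 fold change -0.78, SE 0.21) and Il12b (1.19 ± 0.972 against 6.50 ± 1.49 CPM). Immediate early genes fell beside them (median -0.32, adjusted p = 2.26e-05, adjusted p = 0.485 with an estimated correlation). Monocyte genes fell as well (median -0.62, 17 of 20 lower, adjusted p = 3.85e-06, adjusted p = 0.498 with an estimated correlation). Alternative activation genes fell (median -0.28, adjusted p = 0.00658, adjusted p = 0.485 with an estimated correlation).

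In the same BM-TAM libraries interferon gamma (median 0.89, adjusted p = 0.00209), type I interferon (median 0.33, adjusted p = 0.00609) and MHC class I genes (median 0.45, adjusted p = 5.52e-04) rose against IgG, and adjusted p = 0.606 to 0.641 with an estimated correlation. The guanylate binding protein gene Gbp5 was at 107 ± 122 against 33.4 ± 10.6 CPM and Cd274 at 262 ± 188 against 119 ± 56.1 CPM. Alveolar macrophage genes rose (median 0.49, adjusted p = 9.53e-04, adjusted p = 0.606 with an estimated correlation). B cell (median 1.56, 14 of 15 higher, adjusted p = 1.17e-05) and T cell markers (median 1.31, adjusted p = 0.00167) rose, and adjusted p = 0.546 with an estimated correlation. Gene by gene, edgeR called 1 of 14545 (654 at an unadjusted p under 0.05), DESeq2 3 and limma voom 1. DESeq2 called Sftpc, Slc34a2 and Kank2, and voom Sftpc. Without IgG replicate 1, 3 of 33 lists were called in place of 16. Leaving out any 1 library kept the cytokine, lung epithelial and B cell calls. Lost were the monocyte, alternative activation, interferon gamma, type I interferon, MHC class I, alveolar, immediate early and T cell calls without IgG replicate 1 (medians -0.09, -0.19, 0.32, -0.16, 0.19, -0.03, -0.18 and 0.19); the interferon gamma, type I interferon and MHC class I calls without combination replicate 1 (medians 0.25, 0.07 and 0.07). Without combination replicate 4 the alveolar call was lost too (median 0.40). With sex as a covariate the type I interferon call was lost (median 0.22).

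Against A2V, the combination showed higher interferon and MHC class I genes in BM-TAM. Type I interferon (median 1.31, 20 of 20 higher, adjusted p = 7.58e-13), interferon gamma (median 1.41, 18 of 18 higher, adjusted p = 7.61e-10) and MHC class I genes (median 0.78, 15 of 15 higher, adjusted p = 1.47e-12) rose, and adjusted p = 0.434 to 0.464 with an estimated correlation. No member passed over all genes, while 14, 12 and 11 passed adjusted over the list alone. Mx1 was at 22.9 ± 7.97 against 8.21 ± 4.00 CPM (log2 fold change 1.43, SE 0.37) and the peptide transporter gene Tap1 at 189 ± 139 against 64.3 ± 10.3 CPM. Cd274 was at 262 ± 188 against 119 ± 7.87 CPM. Inflammatory cytokine genes fell (median -0.49, 17 of 18 lower, adjusted p = 8.54e-07, adjusted p = 0.434 with an estimated correlation), with Il1b at 677 ± 152 against 1009.5 ± 139 CPM, as did immediate early genes (median -0.27, adjusted p = 4.40e-05, adjusted p = 0.464 with an estimated correlation). Alternative activation genes fell (median -0.46, adjusted p = 0.0171, adjusted p = 0.464 with an estimated correlation), led by the chemokine genes Ccl22 (12.0 ± 5.02 against 74.4 ± 49.6 CPM) and Ccl17 (36.2 ± 13.1 against 97.7 ± 51.9 CPM), which mature dendritic cells also make. Lung epithelial (median -0.82, adjusted p = 2.87e-05), hypoxia (median -0.22, adjusted p = 6.58e-04) and monocyte genes (median -0.46, adjusted p = 0.00142) fell and B cell markers rose (median 0.66, adjusted p = 4.60e-04), and adjusted p = 0.330 to 0.630 with an estimated correlation. EdgeR called 0 of 14545 genes here (624 at an unadjusted p under 0.05), DESeq2 6 and limma voom 0. The type I interferon, interferon gamma, MHC class I, cytokine, lung epithelial and immediate early calls held with any 1 library left out. Lost were the monocyte and alternative activation calls without A2V replicate 2 (medians -0.19 and -0.10); the monocyte and alternative activation calls without combination replicate 4 (medians -0.28 and -0.30). Without combination replicate 1 the alternative activation and B cell calls were lost too (medians -0.46 and 0.14), and without A2V replicate 1 the hypoxia and B cell calls (medians -0.09 and -0.31). Lost with sex as a covariate were the interferon gamma, cytokine, monocyte, alternative activation, immediate early and B cell calls (medians 0.69, -0.15, 0.13, -0.03, -0.04 and 0.79).

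In T-AM, alveolar macrophage genes rose with A2V against IgG (median 0.20, 18 of 19 higher, adjusted p = 6.50e-05, adjusted p = 0.699 with an estimated correlation), and 2 passed adjusted over the list alone. They were led by Krt19 at 322 ± 45.6 against 187 ± 16.9 CPM and the lysosomal protease gene Ctsk at 962 ± 60.6 against 621 ± 165 CPM (log2 fold change 0.63, SE 0.16). Lipid-associated genes rose (median 0.24, 15 of 16 higher, adjusted p = 2.71e-04), as did hypoxia genes (median 0.35, 15 of 19 higher, adjusted p = 2.71e-04), of which 8 passed higher and 1 lower adjusted over the list alone, and adjusted p = 0.849 with an estimated correlation. The glycolytic genes Pgk1 and Aldoa were at 100.4 ± 21.8 against 69.1 ± 7.89 CPM and 956 ± 134 against 745 ± 29.2 CPM, while Vegfa was at 8.71 ± 3.78 against 22.4 ± 11.6 CPM. Type I interferon (median -1.16, 19 of 19 lower, adjusted p = 8.02e-05) and interferon gamma genes (median -1.50, 17 of 17 lower, adjusted p = 2.95e-04) fell, and adjusted p = 0.849 with an estimated correlation. MHC class II (median -0.48, adjusted p = 0.00118) and class I genes (median -0.31, adjusted p = 0.0150) fell too, and adjusted p = 0.849 with an estimated correlation, with the costimulatory genes Cd80 and Cd86 at 17.4 ± 0.970 against 29.5 ± 8.13 CPM and 9.20 ± 3.10 against 23.6 ± 6.08 CPM. B cell markers rose (median 1.41, adjusted p = 0.00268) and monocyte genes fell (median -0.86, adjusted p = 0.00213), and adjusted p = 0.849 with an estimated correlation. Of 14699 genes tested, edgeR called 0 (1145 at an unadjusted p under 0.05), DESeq2 21 and limma voom 0. With any 1 library left out the alveolar, lipid-associated and B cell calls held. Lost were the type I interferon, interferon gamma, MHC class II, MHC class I and hypoxia calls without IgG replicate 3 (medians -0.82, -0.77, -0.25, -0.04 and 0.33); the type I interferon, MHC class II, MHC class I and monocyte calls without A2V replicate 3 (medians -0.15, -0.30, -0.23 and -0.44). Without A2V replicate 2 the hypoxia call was lost too (median 0.21). The type I interferon, interferon gamma, MHC class II, MHC class I, lipid-associated and hypoxia calls were lost with sex as a covariate (medians -0.60, -0.88, -0.19, 0.13, 0.12 and 0.28).

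With the combination against IgG, genes of lymphocytes, which the gate does not select, rose in T-AM libraries. B cell markers rose (median 2.45, 15 of 15 higher, adjusted p = 4.16e-11), 12 passing adjusted over the list alone, as did T cell markers (median 0.94, adjusted p = 4.73e-05) and the follicular helper and lymphoid structure list (median 1.76, adjusted p = 7.66e-04), and adjusted p = 0.792 with an estimated correlation. MHC class I genes rose (median 0.42, adjusted p = 2.15e-04), and cell cycle genes fell (median -0.12, adjusted p = 0.0102), and adjusted p = 0.863 with an estimated correlation. Gene by gene, edgeR called 0 of 14699 (664 at an unadjusted p under 0.05), DESeq2 13 and limma voom 0. Leaving out any 1 library kept the T cell, B cell and follicular helper calls. Lost were the MHC class I and cell cycle calls without combination replicate 1 (medians 0.16 and -0.09); the MHC class I call without IgG replicate 1 (median 0.08). Without IgG replicate 2 the cell cycle call was lost too (median -0.10), and without IgG replicate 3 the cell cycle call (median -0.09). Without combination replicate 4 the cell cycle call was lost too (median -0.09). All 5 held with sex as a covariate. Without combination replicate 1, 4 lists were called in place of 7.

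Against A2V, interferon gamma genes rose in T-AM with the combination (median 2.02, 17 of 17 higher, adjusted p = 2.58e-07), 16 passing adjusted over the list alone, among them Gbp8 at 53.5 ± 41.7 against 11.4 ± 2.08 CPM (log2 fold change 2.21, SE 0.56) and Gbp3 at 95.1 ± 87.7 against 13.9 ± 3.88 CPM. Type I interferon (median 1.45, 19 of 19 higher, adjusted p = 5.45e-08), MHC class I (median 0.70, adjusted p = 8.36e-09) and MHC class II genes (median 0.53, adjusted p = 5.23e-06) rose too, and for all 4 lists adjusted p = 0.538 with an estimated correlation. Hypoxia genes fell (median -0.20, adjusted p = 7.81e-04, adjusted p = 0.538 with an estimated correlation), 8 passing adjusted over the list alone. Alveolar (median -0.11, adjusted p = 9.79e-04), lipid-associated (median -0.22, adjusted p = 1.01e-04) and cell cycle genes (median -0.26, adjusted p = 1.39e-04) fell, and adjusted p = 0.538 with an estimated correlation. Ctsk was at 579 ± 76.2 against 962 ± 60.6 CPM (log2 fold change -0.73, SE 0.15). Monocyte genes (median 0.59, adjusted p = 9.06e-04) and B cell markers (median 0.88, adjusted p = 0.00221) rose, and adjusted p = 0.538 with an estimated correlation. EdgeR called 0 of 14699 genes here (1334 at an unadjusted p under 0.05), DESeq2 38 and limma voom 0. The type I interferon, interferon gamma, MHC class II, MHC class I, lipid-associated, alveolar and cell cycle calls held with any 1 library left out. Lost was the hypoxia call without A2V replicate 2 (median -0.08); the monocyte call without A2V replicate 3 (median 0.24). The B cell call also failed without combination replicate 1 (median 0.34). Lost with sex as a covariate were the interferon gamma, MHC class II, MHC class I, hypoxia, lipid-associated and B cell calls (medians 0.82, 0.36, 0.24, -0.22, -0.05 and 0.75).

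In CD4 T cells, type I interferon genes fell with A2V (2 mice) against IgG (3 mice): median -0.80, 20 of 20 lower, adjusted p = 2.14e-08, and adjusted p = 0.398 with an estimated correlation. 6 passed adjusted over the list alone. The antiviral genes Oas3 and Ifit3 were at 15.4 ± 1.09 against 37.7 ± 12.8 CPM and 3.34 ± 0.581 against 12.7 ± 6.74 CPM. Interferon gamma genes fell (median -0.34, adjusted p = 8.19e-05). Th1 and cytotoxic genes fell (median -0.36, adjusted p = 9.40e-04) and naive and central memory genes rose (median 0.24, adjusted p = 9.40e-04), and adjusted p = 0.458 with an estimated correlation. The death ligand gene Fasl was at 19.9 ± 2.91 against 43.4 ± 20.4 CPM, granzyme Gzmb at 7.70 ± 1.61 against 15.2 ± 6.01 CPM and the quiescence factor gene Klf2 at 283 ± 33.9 against 168 ± 25.7 CPM. Th2 and Th17 genes fell (median -0.33, adjusted p = 0.0103). Follicular helper and lymphoid structure genes rose (median 0.35, adjusted p = 0.0242), led by Fcer2a and Lta. B cell markers rose beside them (median 1.06, adjusted p = 1.87e-10). Lipid-associated (median -0.89, adjusted p = 1.73e-08) and alveolar macrophage genes (median -0.86, adjusted p = 8.29e-06) fell. Apart from Th1 and naive genes, adjusted p = 0.398 with an estimated correlation. The gate selects neither B cells nor macrophages, and their share in these lists was not tested. Of 17329 genes tested, edgeR called 0 (1209 at an unadjusted p under 0.05), DESeq2 16 and limma voom 0. Without A2V replicate 2, 126 genes were called from an A2V arm of 1 mouse, whose library is under 5 M counts and is assumed to vary like the other groups. Without IgG replicate 3, 1 gene was called. With any 1 library left out the type I interferon, interferon gamma, B cell, lipid-associated and alveolar calls held. Lost were the Th1, naive T cell and Th2 and Th17 calls without IgG replicate 2 (medians -0.19, 0.05 and -0.18); the Th1, Th2 and Th17 and follicular helper calls without A2V replicate 2 (medians -0.07, -0.32 and 0.34). Without A2V replicate 3 the follicular helper call was lost too (median 0.33). The interferon gamma, Th1, naive T cell and Th2 and Th17 calls were lost with sex as a covariate (medians -0.14, 0.07, -0.09 and -0.29).

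With the combination against IgG, interferon genes rose and Th2 and Th17 genes fell in CD4 T cells. For interferon gamma genes (median 0.48, 17 of 18 higher, adjusted p = 5.89e-10, adjusted p = 0.395 with an estimated correlation) 3 passed adjusted over the list alone. Type I interferon genes rose (median 0.37, adjusted p = 6.07e-06, adjusted p = 0.447 with an estimated correlation). For Th2 and Th17 genes (median -0.41, 10 of 15 lower, adjusted p = 2.57e-04, adjusted p = 0.395 with an estimated correlation) the Th17 regulator gene Rorc was at 18.6 ± 2.34 against 27.9 ± 9.12 CPM and the chemokine receptor gene Ccr6 at 37.7 ± 9.85 against 58.6 ± 18.4 CPM. Regulatory T cell (median 0.15, adjusted p = 0.0378) and checkpoint genes (median 0.31, adjusted p = 0.0381) rose, and adjusted p = 0.562 to 0.691 with an estimated correlation. Cell cycle genes rose (median 0.18, adjusted p = 0.0270, adjusted p = 0.691 with an estimated correlation). B cell (median 0.79, adjusted p = 1.01e-11) and plasma cell markers (median 0.60, adjusted p = 2.68e-04) rose too, and adjusted p = 0.395 to 0.447 with an estimated correlation. Gene by gene, edgeR called 0 of 17329 (622 at an unadjusted p under 0.05), DESeq2 3 and limma voom 0. Those of DESeq2 were the immunoglobulin genes Ighm, Igkv5-43 and Igkv8-28. Without IgG replicate 3, edgeR called 1 gene. Leaving out any 1 library kept the interferon gamma, Th2 and Th17 and B cell calls. Lost were the type I interferon, checkpoint, regulatory T cell and cell cycle calls without IgG replicate 1 (medians 0.08, 0.09, 0.05 and 0.01); the checkpoint, regulatory T cell, cell cycle and plasma cell calls without combination replicate 1 (medians 0.05, 0.07, 0.01 and 0.12). Without IgG replicate 3 the checkpoint and regulatory T cell calls were lost too (medians 0.21 and 0.08), and without combination replicate 4 the checkpoint and cell cycle calls (medians 0.38 and 0.13). Without combination replicate 3 the regulatory T cell call was lost too (median 0.15), and without IgG replicate 2 the cell cycle call (median 0.13). All 8 held with sex as a covariate.

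Among the 3 comparisons of CD4 T cells, the combination against A2V gave the largest interferon medians. Type I interferon (median 1.29, 20 of 20 higher, adjusted p = 3.61e-19) and interferon gamma genes (median 0.78, 18 of 18 higher, adjusted p = 4.98e-19) rose, 13 and 10 passing adjusted over the list alone, and adjusted p = 0.270 with an estimated correlation. Tgtp2 was at 83.1 ± 14.3 against 29.6 CPM (log2 fold change 1.49, SE 0.23, adjusted p = 0.128 by edgeR), the A2V libraries differing by less than 0.1 CPM and Oas3 at 40.2 ± 5.72 against 15.4 ± 1.09 CPM. Th1 and cytotoxic genes rose (median 0.43, adjusted p = 5.90e-05) and naive and central memory genes fell (median -0.33, 14 of 14 lower, adjusted p = 4.14e-08), and adjusted p = 0.388 to 0.470 with an estimated correlation. Gzmb was at 18.7 ± 6.09 against 7.70 ± 1.61 CPM, Fasl at 41.4 ± 14.9 against 19.9 ± 2.91 CPM and Klf2 at 202 ± 60.2 against 283 ± 33.9 CPM. Regulatory T cell (median 0.34, adjusted p = 2.07e-04) and checkpoint genes (median 0.32, adjusted p = 0.00752) rose, and adjusted p = 0.388 with an estimated correlation. The transcription factor gene Ikzf2 was at 214 ± 18.5 against 149.7 ± 20.5 CPM, Tigit at 62.7 ± 28.7 against 30.3 ± 13.8 CPM and Cd274 at 87.1 ± 25.9 against 48.3 ± 1.75 CPM. Plasma cell markers (median 1.16, adjusted p = 2.71e-04) and lipid-associated macrophage genes (median 0.83, adjusted p = 1.00e-09) rose too, and adjusted p = 0.373 to 0.388 with an estimated correlation. EdgeR called 0 of 17329 genes here (1014 at an unadjusted p under 0.05), DESeq2 45 and limma voom 1. The voom gene was Gm25890. Without A2V replicate 2 (an A2V arm of 1 mouse) edgeR called 118 genes, without IgG replicate 1, 2, and without IgG replicate 2, 1. The type I interferon, interferon gamma, naive T cell, plasma cell and lipid-associated calls held with any 1 library left out. Lost was the Th1 call without A2V replicate 2 (median 0.19); the regulatory T cell call without A2V replicate 3 (median 0.05). The checkpoint call also failed without combination replicate 1 (median 0.13). Lost with sex as a covariate were the naive T cell, Th1 and checkpoint calls (medians -0.07, -0.11 and 0.12).

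In total tumour cells, cytotoxic lymphocyte and interferon genes fell with A2V against IgG. CD8 T and NK cell genes fell (median -0.93, 17 of 17 lower, adjusted p = 2.16e-08, adjusted p = 0.388 with an estimated correlation), with granzyme Gzmb, the 1 member passing adjusted over the list alone, at 12.5 ± 3.94 against 43.9 ± 22.0 CPM (log2 fold change -1.81, SE 0.44) and perforin Prf1 at 12.5 ± 0.599 against 37.5 ± 24.6 CPM. In male mice alone, with 1 IgG mouse, Prf1, Gzma and Cd3g turned to log2 fold changes of 0.45, 0.56 and 0.16. Type I interferon (median -1.04, 20 of 20 lower, adjusted p = 8.00e-11), interferon gamma (median -0.87, 19 of 19 lower, adjusted p = 2.16e-08) and MHC class I genes (median -0.47, 15 of 15 lower, adjusted p = 4.81e-08) fell, and adjusted p = 0.388 with an estimated correlation. The chemokine gene Cxcl9 was at 4.23 ± 3.43 against 29.3 ± 24.7 CPM. Endothelial (median -0.39, 19 of 20 lower, adjusted p = 4.32e-04), T cell (median -0.42, adjusted p = 0.00178) and erythroid genes (median -1.18, adjusted p = 3.90e-05) fell, and adjusted p = 0.388 to 0.613 with an estimated correlation. Alveolar macrophage genes rose (median 0.36, 19 of 19 higher, adjusted p = 4.75e-07, adjusted p = 0.388 with an estimated correlation). The airway club cell gene Scgb1a1 was at 94.1 ± 39.4 against 4.02 ± 1.77 CPM (log2 fold change 4.53, SE 0.74, adjusted p = 0.540 by edgeR). It and the ciliated cell regulator gene Foxj1 were the 2 lung epithelial genes that passed adjusted over the list alone, and the list rose (median 0.14, adjusted p = 0.00920, adjusted p = 0.631 with an estimated correlation). Neutrophil genes rose (median 0.24, adjusted p = 0.00185, adjusted p = 0.388 with an estimated correlation). Of 18480 genes tested, edgeR called 0 (434 at an unadjusted p under 0.05), DESeq2 4 and limma voom 0. DESeq2 called Scgb1a1, Rnu1a1, A230057D06Rik and Xist, the last a difference of sex. Without IgG replicate 1 and without IgG replicate 3 edgeR called 3 genes, and without combination replicate 2, 1. With any 1 library left out the type I interferon, interferon gamma, MHC class I, CD8 T and NK cell and erythroid calls held. Lost were the T cell, lung epithelial and neutrophil calls without A2V replicate 1 (medians -0.38, -0.21 and -0.04); the T cell and lung epithelial calls without IgG replicate 2 (medians -0.08 and 0.03). Without IgG replicate 3 the T cell and lung epithelial calls were lost too (medians -0.20 and -0.22), and without A2V replicate 3 the alveolar and endothelial calls (medians 0.19 and -0.10). The endothelial call also failed without IgG replicate 1 (median -0.08). The interferon gamma, MHC class I, CD8 T and NK cell, T cell, lung epithelial and erythroid calls were lost with sex as a covariate (medians -0.38, -0.13, -0.43, 0.04, -0.47 and -0.64).

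With the combination against IgG, neutrophil genes rose in total cells (median 0.83, 16 of 16 higher, adjusted p = 2.87e-12, adjusted p = 0.127 with an estimated correlation), and 8 passed adjusted over the list alone. The calprotectin genes S100a9 and S100a8 were at 503 ± 130.2 against 206 ± 11.5 CPM (log2 fold change 1.29, SE 0.24) and 162 ± 38.5 against 67.2 ± 2.72 CPM (log2 fold change 1.27, SE 0.25), and the chemokine receptor gene Cxcr2 at 111 ± 33.3 against 54.1 ± 3.45 CPM. Endothelial genes fell (median -0.71, 20 of 20 lower, adjusted p = 7.30e-07, adjusted p = 0.728 with an estimated correlation), with Mmrn2 at 8.24 ± 0.380 against 24.0 ± 9.36 CPM. The angiogenic tip cell list fell (median -0.99, adjusted p = 0.01, adjusted p = 0.728 with an estimated correlation). Type I interferon (median 0.59, adjusted p = 7.30e-07) and MHC class I genes (median 0.29, adjusted p = 5.21e-04) rose, and adjusted p = 0.728 to 0.751 with an estimated correlation. Monocyte genes rose (median 0.22, adjusted p = 0.0405, adjusted p = 0.728 with an estimated correlation). Alveolar macrophage genes rose (median 0.37, adjusted p = 4.40e-04) and lung epithelial genes fell (median -0.62, adjusted p = 0.00388), and adjusted p = 0.751 to 0.826 with an estimated correlation. Scgb1a1 was at 35.3 ± 27.0 against 4.02 ± 1.77 CPM. Gene by gene, edgeR called 0 of 18480 (894 at an unadjusted p under 0.05), DESeq2 11 and limma voom 0, those of DESeq2 including S100a8, S100a9 and Cxcr2. Without combination replicate 2 edgeR called 1 gene, and without IgG replicate 1 camera called 20 lists in place of 12. Leaving out any 1 library kept the neutrophil, endothelial and type I interferon calls. Lost were the tip cell, lung epithelial, MHC class I and alveolar calls without IgG replicate 1 (medians -0.33, -0.06, -0.08 and 0.11); the tip cell, MHC class I and monocyte calls without combination replicate 2 (medians -0.39, 0.16 and 0.07). Without combination replicate 4 the alveolar call was lost too (median 0.04), and without IgG replicate 2 the monocyte call (median 0.24). Without IgG replicate 3 the monocyte call was lost too (median 0.21), and without A2V replicate 3 the monocyte call (median 0.22). Without combination replicate 3 the monocyte call was lost too (median 0.33). With sex as a covariate the monocyte call was lost (median 0.22).

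Against A2V, interferon, cytotoxic and plasma cell genes rose in total cells with the combination. For type I interferon genes (median 1.65, 20 of 20 higher, adjusted p = 3.70e-20, adjusted p = 0.291 with an estimated correlation) all 20 passed adjusted over the list alone, with Oas3 at 71.4 ± 23.3 against 11.1 ± 3.79 CPM (log2 fold change 2.68, SE 0.59). MHC class I (median 0.76, adjusted p = 6.15e-14) and interferon gamma genes (median 1.16, adjusted p = 8.21e-08) rose, 12 of 15 and 12 of 19 passing adjusted over the list alone, and adjusted p = 0.404 to 0.541 with an estimated correlation. CD8 T and NK cell genes rose (median 1.06, 15 of 17 higher, adjusted p = 8.21e-08, adjusted p = 0.541 with an estimated correlation), with Gzmb at 50.7 ± 22.9 against 12.5 ± 3.94 CPM. Plasma cell (median 0.43, adjusted p = 0.00664), neutrophil (median 0.55, adjusted p = 3.71e-05) and monocyte genes (median 0.27, adjusted p = 1.46e-05) rose, and adjusted p = 0.291 with an estimated correlation. The immunoglobulin gene Igkc was at 429 ± 131 against 154 ± 27.5 CPM, S100a9 at 503 ± 130.2 against 216 ± 69.6 CPM and Plac8 at 67.6 ± 17.0 against 13.9 ± 1.47 CPM (log2 fold change 2.29, SE 0.35, adjusted p = 0.210 by edgeR). Lung epithelial genes fell (median -0.78, 19 of 20 lower, adjusted p = 7.73e-08, adjusted p = 0.541 with an estimated correlation). Erythroid genes rose too (median 0.97, adjusted p = 0.00107, adjusted p = 0.541 with an estimated correlation). EdgeR called 0 of 18480 genes here (1177 at an unadjusted p under 0.05), DESeq2 54 and limma voom 0. Without IgG replicate 1, 22 genes and 21 lists were called, and without combination replicate 4, 1 gene. The type I interferon, interferon gamma, MHC class I, CD8 T and NK cell, plasma cell, neutrophil, monocyte and lung epithelial calls held with any 1 library left out. Lost was the erythroid call without A2V replicate 2 (median 0.20); the erythroid call without combination replicate 2 (median 0.35). Lost with sex as a covariate were the CD8 T and NK cell and erythroid calls (medians 0.45 and 0.44).

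**Figure D2:**
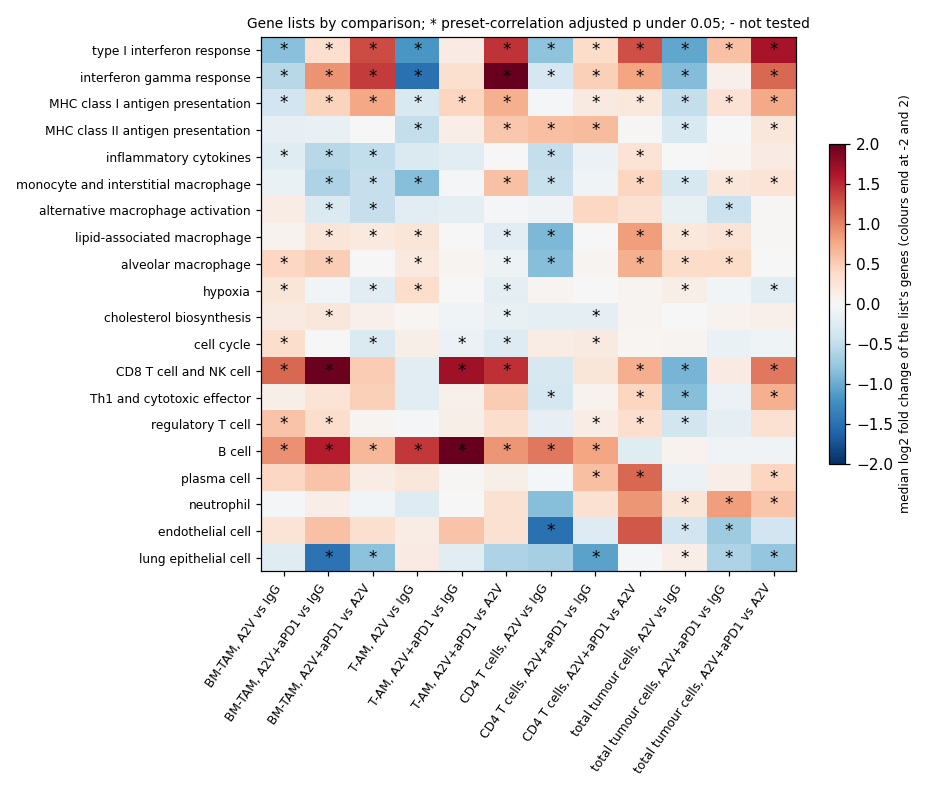
Median log2 fold change of 20 gene lists (vertical axis) in the 12 treatment comparisons (horizontal axis), coloured from -2 to 2, with a star where the adjusted p with the preset correlation was under 0.05.

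**Figure D3:**
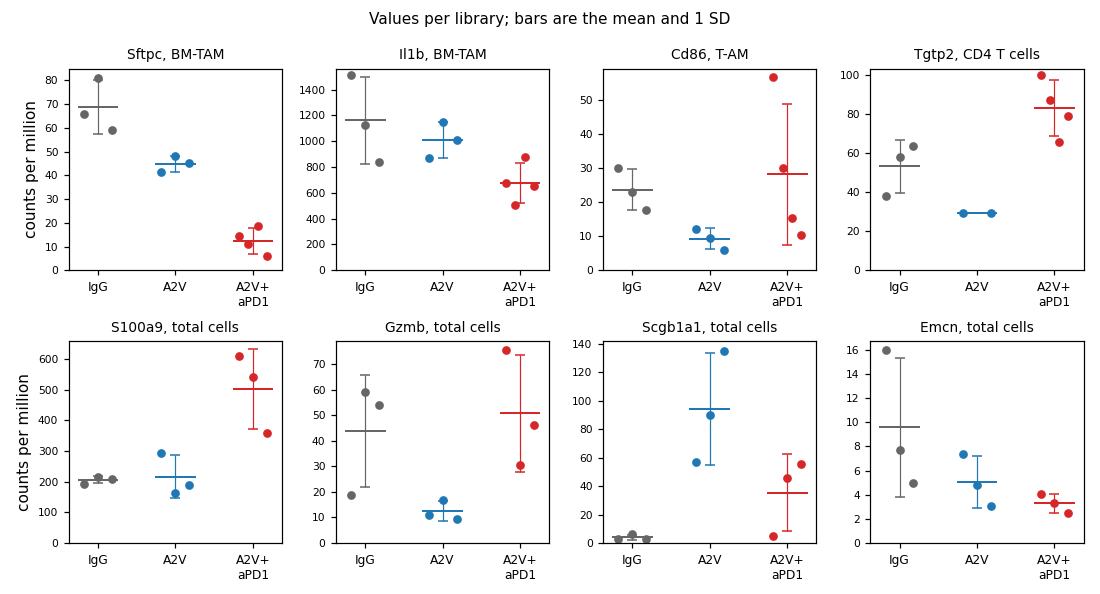
CPM of 8 genes by treatment, a point per library, with the mean and 1 SD as bars.

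Whether BM-TAM and T-AM responded differently was tested directly, as the response in BM-TAM minus that in T-AM. For the combination against IgG that difference was below 0 for inflammatory cytokine (median -0.37, 17 of 18 lower, adjusted p = 0.00185), immediate early (median -0.25, adjusted p = 0.00185) and monocyte genes (median -0.40, adjusted p = 0.0488). It was above 0 for cholesterol biosynthesis (median 0.32, 16 of 18 higher, adjusted p = 0.0174), alveolar (median 0.36, adjusted p = 0.0296) and lipid-associated genes (median 0.21, adjusted p = 0.0468), and for all 6 lists adjusted p = 0.970 with an estimated correlation. All 6 calls were lost without IgG replicate 1 (medians -0.24, -0.11, -0.19, 0.07, -0.03 and 0.03). Monocyte genes also lost theirs without IgG replicates 2 and 3, A2V replicate 3 and combination replicates 1 and 2 (medians to -0.50). Cholesterol genes lost theirs without IgG replicate 2 and combination replicate 2, alveolar genes without combination replicates 2 and 4, and lipid-associated genes without IgG replicate 2 and combination replicates 1 and 4 (medians to 0.25, 0.35 and 0.26). With sex as a covariate the monocyte, alveolar, lipid-associated and cholesterol calls were lost (medians -0.31, 0.28, 0.23 and 0.25). For A2V against IgG camera called 0 of 34 lists. EdgeR called 0 of 15989 genes in both tests (550 for A2V and 637 for the combination at an unadjusted p under 0.05), DESeq2 0 and 0 and limma voom 0 and 0. Same-numbered BM-TAM and T-AM libraries pair in the IgG and combination arms but not in the A2V arm (1 of 3 pairs). With the mouse as a block, camera called 6 lists for A2V and 12 for the combination, and 0 and 0 with an estimated correlation. EdgeR then called 1 gene for the combination (Abca1).

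Lists not given above were called in few of the treatment comparisons that could test them. Mast cell, basophil and eosinophil genes were called in 0 of 9 (medians -0.40 to 0.79, smallest adjusted p 0.0580, and adjusted p = 0.467 with an estimated correlation), and platelet and megakaryocyte genes in 0 of 6 (medians -0.73 to -0.11, smallest adjusted p 0.383, and adjusted p = 0.606 with an estimated correlation). Pericyte and smooth muscle genes were called in 1 of 12 (medians -1.05 to 0.45, smallest adjusted p 0.0131, and adjusted p = 0.388 with an estimated correlation), and fibroblast genes in 2 of 12 (medians -2.46 to 0.50, smallest adjusted p 4.82e-06, and adjusted p = 0.395 with an estimated correlation). Dendritic cell genes were called in 4 of 12 (medians -0.65 to 0.71, smallest adjusted p 0.0195, and adjusted p = 0.398 with an estimated correlation). VEGF and angiopoietin ligands and receptors were called in 2 of 12 (medians -1.0 to 0.97, smallest adjusted p 0.00752, and adjusted p = 0.388 with an estimated correlation), both times in CD4 T cells. In total cells, where the receptors are expressed, that list had a median of -0.10 for A2V and -0.26 for the combination against IgG (adjusted p = 0.558 and 0.739 by camera). The median, mean and test of a list differed in sign in 71 of all 493 list tests and in 0 of the 182 called.

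**Figure D4:**
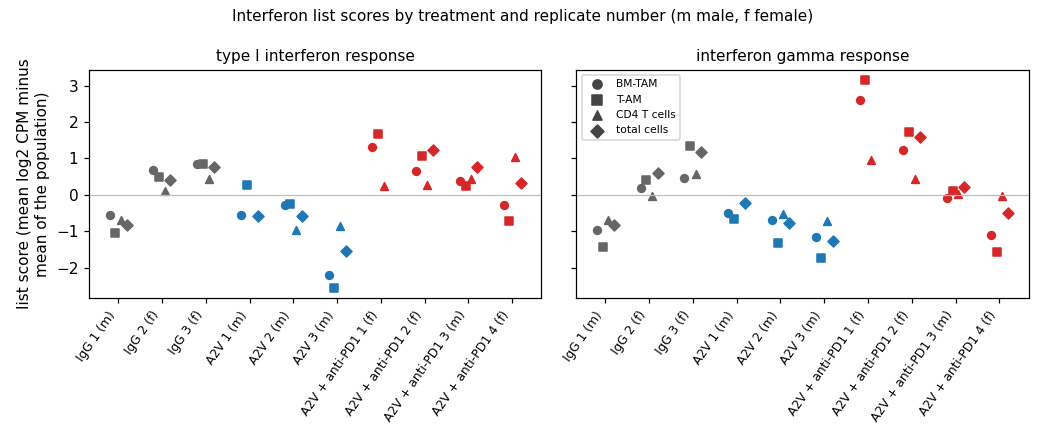
Scores of the type I interferon and interferon gamma lists (vertical axis, log2 units relative to the mean of each population) for each treatment and replicate number (horizontal axis, sex in brackets), a point per population. Averaged over these lists, MHC class I and the populations, the score was 0.05 ± 0.75 in IgG (n = 3), -0.70 ± 0.41 in A2V (n = 3) and 0.55 ± 0.77 in combination mice (n = 4).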

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

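All tests of explanations in this part were chosen after the result was seen, while the regroupings of mice, apart from those without the filter on low counts or with the mouse as a block, were planned before. Libraries far from the others of their group were looked for in groups of 4 by the gap to the nearest library over the range (Dixon's test at 95%). 6 of 122 values passed (4.92%, where chance gives about 1 in 20). In T-AM combination mice the alveolar list score of replicate 2 was -0.14 (others -0.01 to 0.01). In BM-TAM combination mice replicate 4 held 7112420 counts (others 10604400 to 11211700) and replicate 1 had Cd274 at 543 CPM (others 143 to 188). In CD4 T cells of combination mice the checkpoint list score of replicate 1 was 0.68 (others -0.07 to -0.00), Gzmb of replicate 2 was at 27.7 CPM (others 15.0 to 16.8) and Ifit1 of replicate 4 at 40.0 CPM (others 14.8 to 18.8). Only lists described in the report were looked at. Before these were narrowed down, after their values were seen, the cholesterol list score of T-AM combination replicate 1 (-0.31) passed too.

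The difference between the responses of BM-TAM and T-AM to the combination was called for 6 lists with the preset correlation. Its medians were 0.21 for lipid-associated, 0.36 for alveolar, -0.40 for monocyte, -0.37 for inflammatory cytokine, 0.32 for cholesterol and -0.25 for immediate early genes. In 4 cases every library of a treatment moved one way in 1 population and the opposite way in another, and these differences were not tested. The alveolar list score moved by 0.27 in T-AM and by -0.91 in CD4 T cells with A2V against IgG, and by -0.20 and 0.94 with the combination against A2V. The neutrophil list score moved by -0.70 in CD4 T cells and by 0.47 in total cells with A2V against IgG. The inflammatory cytokine score moved by -0.54 in BM-TAM and by 1.24 in CD4 T cells with the combination against A2V.

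Interferon and MHC class I lists lay higher in the combination than in A2V in all 4 populations: all 12 list medians were above 0, with a median of 1.22. Averaged over populations, the score was 0.55 ± 0.77 in the 4 combination mice and -0.70 ± 0.41 in the 3 A2V mice, against 0.05 ± 0.75 in the 3 IgG mice. Leaving out any 1 replicate number kept at least 71.3% of the median (without A2V replicate 3), so a single mouse does not account for it. Chance differences between mice stay open, with a two-sided exact permutation p of 0.0571 (2 of 35 splits; the smallest possible is 0.0286) and an adjusted p of 0.114 over 4 comparisons. Sex stays open too and may account for part or all of it: with sex as a covariate 47.0% of the median was kept (0.58, all 12 still above 0), and over all treatments the 5 female mice scored 0.59 ± 0.66 and the 5 male mice -0.53 ± 0.50 (exact permutation p = 0.0159, adjusted p = 0.0635), a test that cannot part sex from treatment, since all 3 A2V mice are male and 3 of the 4 combination mice female.

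Neutrophil genes were higher in total cells with the combination against IgG (median 0.83, SE 0.43 over genes, edgeR log2 fold changes). The endothelial median (-0.70, SE 0.13, 20 of 20 genes lower), which A2V may lower, cannot exclude a lower share of the main cell type. More blood in the suspension could raise neutrophils, and it cannot be told apart from a change in the tumour: the erythroid median was 0.13 (SE 0.17) and the platelet median 0.06 (SE 0.55), both under 0.42, but red cells may have been lysed, which the labels do not state. A rise in tumour neutrophils with treatment stays open and was not tested otherwise.

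Sftpc was lower in BM-TAM with the combination against IgG (log2 fold change -2.45). The other 16 lung epithelial genes tested there had a median of -1.27 (SE 0.27), past 0.5 of the Sftpc change (-1.22), so less RNA carried over from alveolar epithelial cells is a candidate explanation, although the CD45 and F4/80 gates should remove such cells. Lower Sftpc in the tumours as a whole does not account for it, since in total cells the log2 fold change was -0.61 (SE 0.32), and 2 SE below it is -1.25. A change of Sftpc within BM-TAM was not tested apart from these.

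Other groupings of the same mice show how far chance can be excluded. Where the real count of genes is 0, every grouping reaches it (35 of 35 or 10 of 10) and nothing is tested. This holds for both response differences and all treatment comparisons regrouped, except the combination against IgG in BM-TAM. There 3 of 35 (real 1, highest other 12) groupings gave at least as many genes. For lists the number was 3 of 35 (real 16, highest other 17) for the combination against IgG and 6 of 35 (real 14, highest other 17) against A2V in BM-TAM, 26 of 35 (real 7, highest other 19) and 7 of 35 (real 13, highest other 19) in T-AM, 11 of 35 (real 15, highest other 20) for the combination against IgG in CD4 T cells and 9 of 35 (real 6, highest other 9) for the response difference with the combination. With the mouse as a block the last was 17 of 35 (real 12, highest other 22) for lists and 5 of 35 (real 1, highest other 6) for genes. Chance is excluded in none of these. Groupings with 31 genes in T-AM (combination and A2V), 94 in total cells (A2V and IgG) and 12 in BM-TAM (combination and IgG) are the highest of all groupings, and point to a structure of the mice other than treatment or to an extreme grouping, which was not tested.

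Comparisons of 3 against 3 have 10 groupings, too few for a share under 0.05. For A2V against IgG those with at least as many lists were 3 of 10 (real 11, highest other 13) in BM-TAM, 8 of 10 (real 9, highest other 12) in T-AM and 3 of 10 (real 18, highest other 25) in total cells. In total cells the combination gave 9 of 10 (real 12, highest other 23) against IgG and 5 of 10 (real 13, highest other 22) against A2V, and the response difference with A2V, which called 0 lists, had at most 8 in another grouping and with the mouse as a block gave 9 of 10 (real 6, highest other 14). BM-TAM against T-AM gave 1 of 10 (real 930, highest other 0) for genes and 3 of 10 (real 15, highest other 17) for lists, and the 3 groupings that part as many replicate pairs as the real one gave at most 0 genes and 11 lists. CD4 T cells with A2V (2 mice) were not regrouped. Without the filter on low counts, the combination against A2V gave as many genes in 5 of 35 groupings in BM-TAM (real 207, highest other 264), 4 of 35 in T-AM (real 519, highest other 821) and 1 of 10 in total cells (real 447, highest other 350), the last too few groupings to exclude chance.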

How the results depend on the processing

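The alternatives named at the start as added later were chosen after the result was seen. Counts for the treatment comparisons follow the order A2V against IgG, the combination against IgG and the combination against A2V. The genes called by DESeq2 were 1, 3 and 6 in BM-TAM, 21, 13 and 38 in T-AM, 16, 3 and 45 in CD4 T cells and 4, 11 and 54 in total cells, and no filter on low counts gave 60, 173 and 207 in BM-TAM, 351, 232 and 519 in T-AM, 190, 101 and 159 in CD4 T cells and 101, 300 and 447 in total cells. For BM-TAM against T-AM, DESeq2 called 1765, no filter 1879, all 20 macrophage libraries 1502 and leaving out libraries under 5 M counts 244, and for the 2 response differences no filter gave 96 and 41. Male mice alone gave 5, 93, 186 and 4 genes in the 4 populations for A2V against IgG, with an IgG arm of 1 library that is assumed to vary like the A2V libraries. The Sftpc call was lost (0 genes) with only the 2 arms compared, in female mice alone and without libraries under 5 M counts. For the combination against A2V, only the 2 arms compared gave 2 genes in CD4 T cells and 6 in total cells, and in CD4 T cells limma voom gave 1 and robust moderation 1 (Tgtp2). Data simulated without change gave 0 to 5 genes per treatment comparison in DESeq2, 0 to 23 without the filter and 0 to 5 in edgeR. The cause of these shifts was not tested.

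With an estimated correlation 0 lists were called in every comparison. With sex as a covariate the list counts fell to 8 in BM-TAM and 6 in T-AM for the combination against A2V, 10 in total cells for A2V against IgG and 2 for the response difference with the combination, which had 3 without libraries under 5 M counts. Medians that changed sign with sex as a covariate were MHC class I 0.0603 in BM-TAM and 0.13 in T-AM, Th1 0.0730 and naive T cell -0.0865 in CD4 T cells, and T cell 0.0401 and lung epithelial -0.47 in total cells for A2V against IgG, and monocyte 0.13 in BM-TAM and Th1 -0.11 in CD4 T cells for the combination against A2V. In male mice alone, against the single IgG replicate 1, Spp1 turned to 0.21 in BM-TAM, and Prf1 to 0.45, Gzma to 0.56 and Cd3g to 0.16 in total cells.

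With the replicate number as a block BM-TAM against T-AM gave 1629 genes. Across treatments no set met the pairing rule. There the block gave 3 genes (Igha, Nos2 and Sftpc) in BM-TAM for the combination against IgG, 1 (Ccr5) in T-AM for A2V against IgG, and for the combination against A2V 4 (Ccr5, Cd86, Mmp14 and Pla2g7) in T-AM and 1 (Ifitm3) in total cells. Blocked list counts were 13 and 23 in T-AM and 24 in total cells, and for the combination against IgG in total cells the alveolar median turned to -0.16 and the endothelial median, whose direction in the test held, to 0.0570. With the mouse as a block the response differences gave 6 and 12 lists, 0 with an estimated correlation, and 1 gene (Abca1) for the combination, which pairing backs. Apart from fits without 1 library, every other count of calls stayed within 1.5 times the reported one.

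Leaving out 1 library gave 179 to 1782 genes for BM-TAM against T-AM, 0 to 2 in BM-TAM for the combination against IgG, 0 to 126, 0 to 1 and 0 to 118 in CD4 T cells and 0 to 3, 0 to 1 and 0 to 22 in total cells, with a lone A2V library in CD4 T cells assumed to vary like the other groups. List counts were 6 to 12 and 3 to 17 in BM-TAM against IgG, 4 to 10 in T-AM for the combination against IgG, 11 to 20 and 10 to 21 in total cells for the combination, and 0 to 4 and 1 to 6 for the response differences. Values that changed sign and direction were, without BM-TAM IgG replicate 1, cytokine 0.0574 (range -0.40 to 0.0574) and alveolar -0.13 (range -0.13 to 0.85) for A2V and type I interferon -0.16 (range -0.16 to 0.64) and alveolar -0.0277 (range -0.0277 to 0.94) for the combination. Without BM-TAM IgG replicate 3 Spp1 was 0.0395 (range -1.81 to 0.0395) and 0.33 (range -1.52 to 0.33), and without A2V replicate 1 B cell genes were -0.31 (range -0.31 to 1.27) for the combination against A2V. In total cells lung epithelial genes were -0.22 (range -0.22 to 0.65) without IgG replicate 3 and MHC class I -0.0770 (range -0.0770 to 0.51) without IgG replicate 1, and of the response differences the alveolar median was -0.0350 (range -0.0350 to 0.82) without IgG replicate 1. There camera's direction for lipid-associated genes turned while the median stayed above 0 at 0.0347 (range 0.0347 to 0.46). Medians of -0.21 (lung epithelial) and -0.0379 (neutrophil) in total cells without A2V replicate 1, and of -0.14 (interferon gamma) for BM-TAM against T-AM without T-AM IgG replicate 1, changed sign while the direction in the test held. Over all alternatives 6 of 4974 gene values and 18 of 1601 list values changed direction in the test.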

Other observations

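Both tests in this part were chosen after a result was seen: that of the interferon scores after the scores, and that of the airway genes after Scgb1a1 and Foxj1 but before the values of the genes tested. Airway epithelial genes were looked at in total cells for A2V against IgG beside Scgb1a1. Of 24 genes of club and ciliated cells, 21 could be tested, and 20 of them were higher with A2V (median log2 fold change 1.21, SE 0.31 over genes). The 12 ciliated cell genes were all higher, and the 9 club cell genes had a median of 0.75, 8 higher. With the combination against IgG the median was 0.41, with 13 of 21 higher. No gene passed the edgeR test (smallest adjusted p = 1), and many lie near 1 CPM with large spread. Set against all other genes by limma camera, the 21 genes gave p = 3.78e-06 with the preset correlation and p = 0.0557 with an estimated one, a test added after the values were seen. Without any 1 library 18 to 20 genes were higher and the median was 0.77 (A2V replicate 2) to 1.42 (A2V replicate 3; preset p at most 0.00472, estimated 0.00871 to 0.185), so a single library does not account for the rise. The median fell under the value of 1 set for this explanation without A2V replicates 1 and 2 and IgG replicate 3. More airway epithelial cells in the A2V suspensions, which dissection could bring, stay a possibility, and a change in the tumours was not tested.

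Interferon scores of libraries with the same treatment and replicate number mostly moved together across populations. Over 12 relations (2 lists and 6 pairs of populations, 8 to 10 mice each), Pearson's r was 0.52 to 0.98 (median 0.92) and Spearman's rho 0.32 to 1. By 100000 permutations, 10 of 12 passed for r and 9 of 12 for rho after Benjamini-Hochberg adjustment, with adjusted p from 8.27e-05 to 0.155 and from 1.20e-04 to 0.410. Without the 2 mice farthest from the median r was 0.29 to 0.99 (median 0.83). Within treatment arms r was -0.01 to 0.98 (median 0.92), and 9 of 12 passed (smallest adjusted p 0.00926, exact permutation). The 3 that failed are those of type I interferon scores with CD4 T cells (r -0.01 to 0.37). A state shared by the libraries of 1 mouse, or of 1 processing day, is a candidate explanation, and these cannot be separated, since the labels give no processing days. If so, the populations are not independent evidence for an interferon difference between treatments, apart from type I interferon in CD4 T cells, where this was not shown.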
